A study of Mus musculus with 14 samples.

How the data were processed

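Single cells from blood, lung and culture were amplified by MALBAC and sequenced as DNA libraries, and the deposited coverage table gives 648 cells over 4880 genome bins of variable width (median 538 kb). The values are a normalised coverage signal that the authors computed per bin and cell, and the autosomal medians of the cells gather near a few levels. Per the submitters' processing notes the tools of the series were Trim Galore, BWA, Picard, SAMtools, HISAT2 and featureCounts with the mm10 build, and the last 2 of these serve RNA. The deposited values are never 0 or negative. Each cell's autosomal median was divided by that of naive WBC and rounded to a whole number. This gave 5 levels, with medians near 1.82 (244 cells), 3.72 (317), 5.64 (61), 7.75 (10) and 9.59 (16). The highest median counted near 1.82 was 2.44, which lies between levels. The values of most cells stop at exactly 10, with 26 cells holding values above it. The settings of the bins, the levels and this ceiling are not stated in the descriptions. Read counts per cell are not part of the coverage values, so the depth is unknown, no interval was computed from reads, and the bin-to-bin noise of each cell stands in for its precision. No pair of cells shared all values, and the highest correlation between cells was 0.959.

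Each cell's class, tissue and batch were taken from the deposited cell table, whose 648 identifiers match the coverage columns. The batch label is the sample, and classes of 1 sample share that label, which is the source of the pairing. The ceiling makes high bins incomparable between levels, so bins at 10 in at least 1% of cells were left out, 304 of 4424 autosomal and 34 of 290 X bins, a decision taken after the values were seen. Before this 2.62% of values stood at the ceiling, and 0.0140% did in the bins kept. The 4120 autosomal and 256 X bins left were put on the log2 scale after adding a pseudocount of 0.1 to the deposited values, and the cell's autosomal median was subtracted, so that the level of a cell drops out except that the pseudocount weighs more at a low level. Values at single loci were divided by the autosomal median without a pseudocount. The 166 bins of Y were not tested.

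The copy-number tumor score is the slope of a cell's autosomal log2 profile on the difference of the mean culture and naive WBC profiles. A score above 0.5 was called tumor-like and one from 0.25 to 0.75 intermediate, so that a cell can be both. The X level is the median log2 value of X bins, and the noise is the median absolute difference of neighbouring autosomal bins. Cells of 1 class in 1 sample were averaged, and samples with at least 3 cells of both classes were paired. This left 5 samples for each class comparison, namely C1L, C1N, C1R, C2R and C3R. Samples P1, P2 and P4 held DP cells only, so no class comparison covers them. Differences were tested by two-sided exact sign-flip permutation tests with the sample as the pair. For single bins, the class means of each sample were fitted with limma (lmFit and eBayes) with the sample as a block, and 4376 bins were adjusted by Benjamini-Hochberg at 5%. Shares of cells carry exact Clopper-Pearson 95% intervals. A count of 0 is given with the share that 3 cells would make, which lies below the upper end of the exact interval. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, matplotlib 3.10.9, R 4.3.3 and limma 3.58.1 were used.

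Before the data were examined, the comparisons, tests, score limits, gene lists and most alternatives were fixed, as was the rule for named genes. That rule took 47 genes in 4 lists (melanocyte lineage, growth signalling, cell cycle and tumor suppressors, leukocyte and antigen presentation), gave each the bin over its midpoint in the mm10 gene annotation, and named with values the 5 per direction with the largest difference between culture and naive WBC and up to 10 past the test in DP minus WBC by adjusted p. Some genes share 1 bin and so count together, namely Cdkn2a with Cdkn2b, and Mlana with Cd274 and Jak2. Genes named outside this rule are members of a list that passed, or the Tcra and Il1rapl1 loci, which were chosen after their values were seen. The leukocyte and antigen presentation list and some genes that the rule would name are not reported here. Runs of altered bins in the culture were taken from a running median of 5 bins, with at least 10 bins and a log2 difference of at least 0.3.

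The bin test was tested on simulated data in which 200 of 4376 bins were changed. It recovered 65%, 59% and 59% of changes of 0.2 and 97%, 99% and 96% of changes of 0.5 for DP minus WBC, CTC minus WBC and CTC minus DP, with 9, 4 and 11 false calls. The simulated noise was independent between bins, and 1048 to 2178 bins passed in the data. These rates therefore need not carry over. The score was tested on simulated mixtures of culture and naive WBC profiles, where 0%, 25%, 50%, 75% and 100% tumor DNA gave mean scores of 0.00421, 0.279, 0.508, 0.763 and 0.997.

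The alternatives left out each sample in turn, changed the minimum number of cells, the pseudocount, the scale, the bins in the score, the score limits, the control profiles and the tissue, kept low-noise cells, or removed the block. Further ones, chosen after seeing the data, put back the bins at the ceiling, restricted DP cells to those near 3.7, or applied the cell minimum and the tissue to the bin tests. The planned shares of tumor and host variants, the share of cells with both, their relation to the score and the cell type markers were not analysed here, since the tables used hold neither variant support nor expression.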

Results

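Single-cell whole-genome DNA libraries were compared to ask which genome the sorted cell classes of tumor-bearing mice carry. The series title speaks of candidate hybrids of tumor cells and leukocytes, and the descriptions neither say which class these are nor spell out DP, CDP, Duplike or PltLike. B16F10 is a metastatic melanoma line of C57BL/6J mice, and the host animals were female C57BL/6J mice injected with labelled B16F10 cells. Cells from blood and lung were sorted into circulating tumor cells (CTC), white blood cells (WBC) and the DP class. Each genome was amplified by MALBAC, which copies the DNA of a single cell in looping cycles before sequencing. Profiles of 648 cells from 14 samples were measured, of which 9 samples came from tumor-injected mice and held 43 CTC (in 5 samples), 450 DP (in 9 samples) and 46 WBC (in 6 samples). The other 5 samples were controls, with 22 cells of the B16F10 culture, 21 WBC of naive mice, and 18 CDP, 24 Duplike and 24 PltLike cells whose labels give the treatment as naive. No read counts accompanied the coverage values used here, so the depth of each cell is unknown. The median absolute difference of neighbouring bins, a measure of evenness that depends on depth, lay between 0.136 and 0.270 on the log2 scale over all cells.

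The culture was compared with naive WBC to find which parts of the genome tell the line from the host. All differences are relative to the autosomal median of each cell and do not give absolute copies. On this scale the line carried more of chromosome 6 than naive WBC (0.55 in log2, 1.46-fold). It also carried more of chromosomes 3 (0.19), 11 (0.17) and 1 (0.16). It carried less of chromosomes 14 (-0.39) and 18 (-0.37), and its X level was -1.22, against -0.0021 in naive WBC. On X the difference fell into a proximal part from 1 to 109216700 at -0.95 and a distal part from 109216701 to 171031299 at -1.85. This boundary was chosen after the profile was seen. The hosts were female and the sex of the line's donor was not examined, so the X level does not by itself show a loss. The donor's sex would act along the whole of X, and the lower distal part argues against it as the only source. CTC also stood lower in the distal part, at -1.72 ± 0.0764 against -0.83 ± 0.0442 proximal (SD, n = 5 samples, relative to naive WBC). Runs of at least 10 neighbouring bins with a difference of at least 0.3 numbered 27, of which 9 were gained (255 Mb) and 18 lost (380 Mb). The 5 most gained runs were chromosome 6 from 3705902 to 42759260 (0.61), chromosome 1 from 25999078 to 64163925 (0.55), chromosome 6 from 45559526 to 149736546 (0.54), chromosome 3 from 72182723 to 91806437 (0.51) and chromosome 12 from 106677522 to 120129022 (0.37). The 5 most lost runs were chromosome 14 from 1 to 52353918 (-0.44), chromosome 5 from 84410385 to 116947591 (-0.41), chromosome 10 from 103559453 to 130694993 (-0.41), chromosome 14 from 54085779 to 89050890 (-0.40) and chromosome 4 from 114073164 to 139045952 (-0.40). Coordinates are positions in mm10 counted from 1. The balance of gains and losses turned with the limit, since 15 gained and 12 lost runs passed 0.2, and 7 gained and 0 lost runs passed 0.5. With at least 20 bins 17 runs were left, 6 gained and 11 lost.

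Among the genes of the fixed lists, those highest in the culture relative to naive WBC included Mitf (0.62), the master transcription factor of melanocytes. Others were Met (0.57), the receptor of hepatocyte growth factor, and the kinase gene Braf (0.57). The lowest were Dct (-0.77), an enzyme of melanin synthesis, Mdm2 (-0.46), which restrains p53, and the chromatin remodelling gene Arid1a (-0.44). Apc (-0.43), a brake on Wnt signalling, and Cdk4 (-0.43), a kinase of the cell cycle, followed. These values are relative to the autosomal median of each cell, so a low value need not mean fewer copies than in the host. Each gene's value is that of the bin over its midpoint, and bins had a median width of 538 kb, so losses shorter than a bin are averaged with their surroundings. The culture and the naive WBC are 1 sample each, so these differences have no error between samples and no test.

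**Figure D1:**
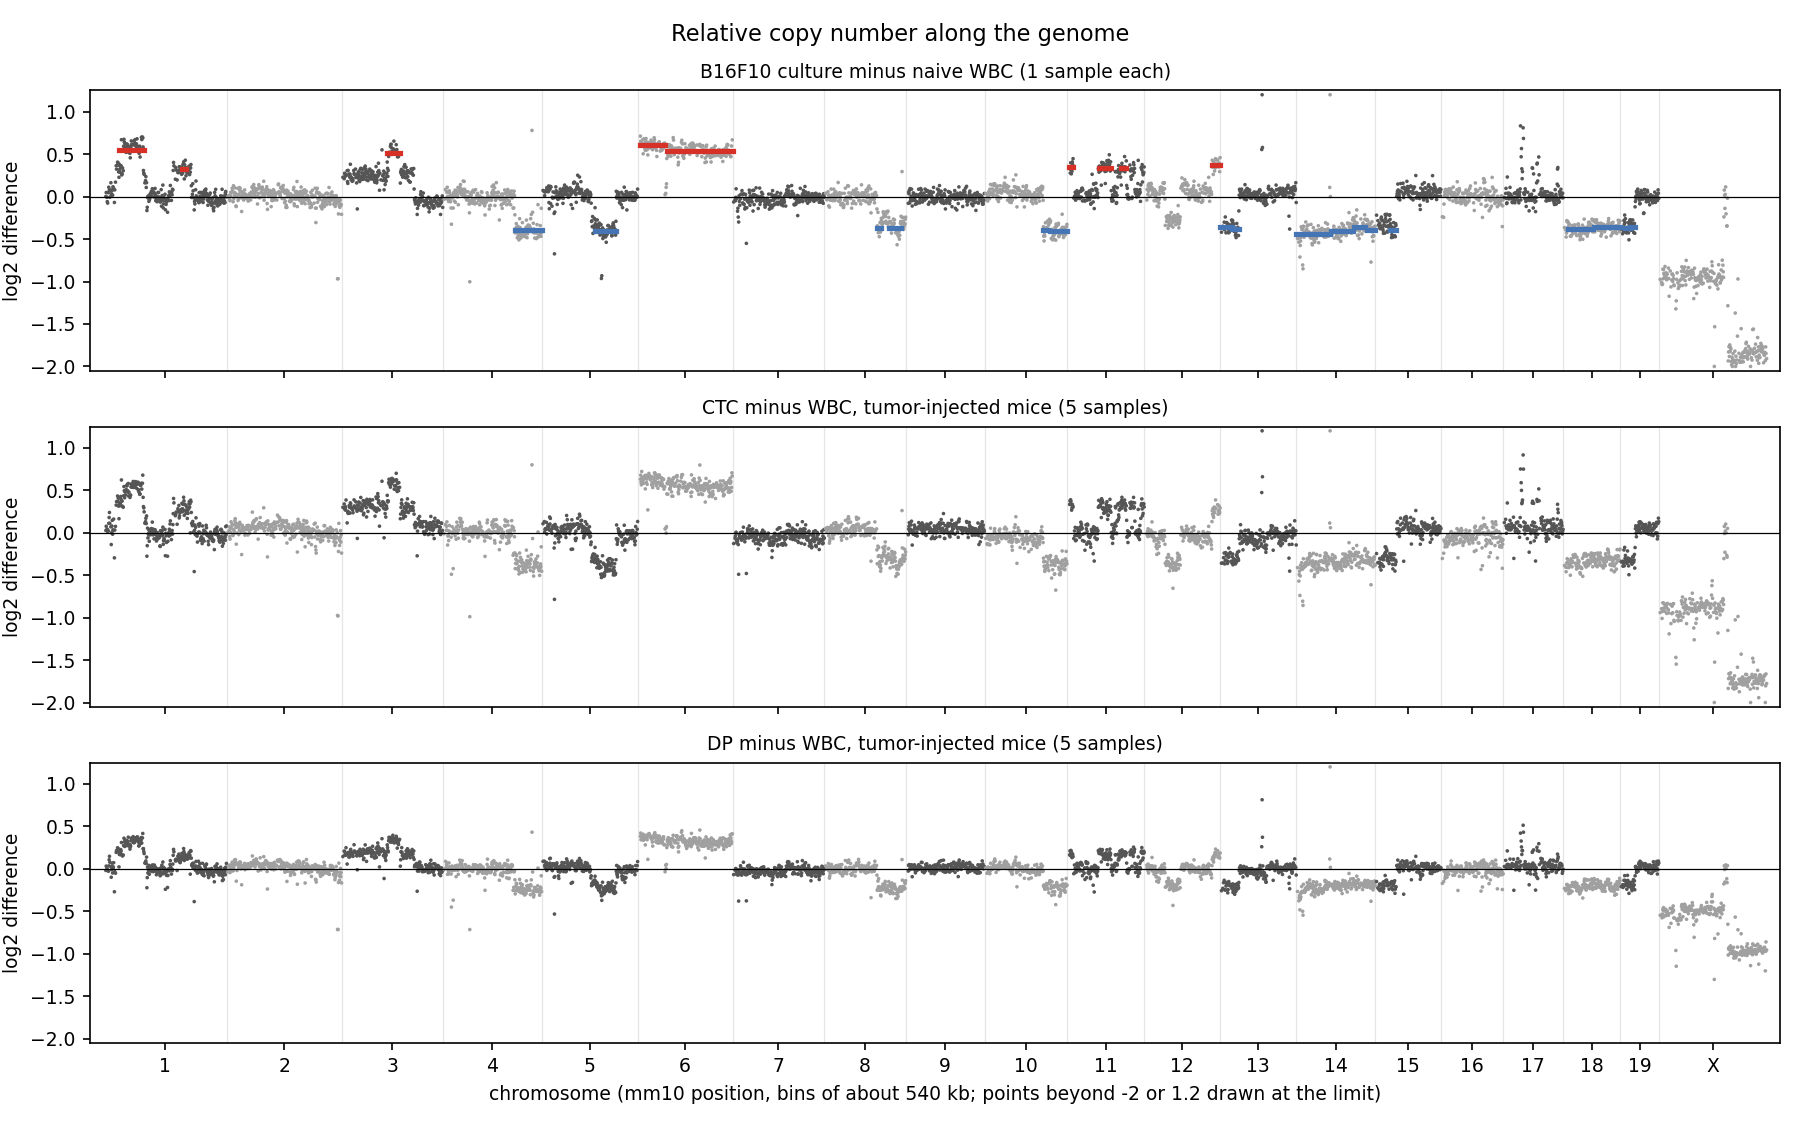
Copy number along chromosomes 1 to 19 and X (horizontal axis, mm10 position) as the log2 difference (vertical axis) of culture minus naive WBC, CTC minus WBC and DP minus WBC, from top to bottom, with 1 point per bin and red and blue bars for the gained and lost runs. The higher level of chromosome 6 and the lower levels of chromosomes 14, 18 and X in the culture are also seen in CTC. These differences are smaller in the mean of DP cells (0.32 on chromosome 6, against 0.56 in CTC).

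CTC were compared with WBC of the same samples to see whether sorted tumor cells keep the profile of the line. CTC stood at 0.55 ± 0.0510 (SD, n = 5 samples) on chromosome 6, at -0.35 ± 0.0330 on chromosome 14 and at -0.33 ± 0.0661 on chromosome 18, relative to naive WBC on the log2 scale. WBC of the same samples stood at -0.0052, -0.020 and 0.0083. The copy-number tumor score, which is 0 at the naive WBC mean and 1 at the culture mean, averaged 0.944 ± 0.0517 (SD, n = 5 samples) in CTC and 0.0113 ± 0.0111 in WBC. Bins of chromosome 6 were higher in CTC at 233 of 237 positions (mean difference 0.56), while 211 of 214 bins of chromosome 14 (mean difference -0.33), all 154 of chromosome 18 (-0.34) and 250 of 256 of X (-1.20) were lower. Of the growth signalling genes 6 of 11 were higher and 0 lower. Of the cell cycle and tumor suppressor genes 1 of 15 was higher and 7 were lower, and of the melanocyte genes 2 of 10 were higher and 4 lower. Adjusted over the list alone, the counts of these lists were the same.

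The difference in score between CTC and WBC was 0.933 ± 0.0521, above 0 in 5 of 5 samples (two-sided exact sign-flip test, p = 0.0625, the smallest p that 5 pairs allow). By limma with the sample as a block, 2178 of 4376 bins passed a false discovery rate of 5%, 879 higher and 1299 lower in CTC. The labels do not say whether each sample is 1 mouse, so every p here measures only the spread between these samples.

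DP cells were compared with WBC of the same samples to ask whether the DP class carries tumor DNA. The DP class was a mixture of cells with the profile of the line, cells with the flat profile of the host and a smaller set between them. Over the 9 samples its mean score was 0.509 ± 0.280 (SD), with sample means from 0.0427 to 0.852. Of the 450 DP cells, 269 (59.8%, exact Clopper-Pearson 95% interval 55.1% to 64.3%) had a tumor-like score above 0.5, and 40 (8.89%, 6.43% to 11.9%) had an intermediate score from 0.25 to 0.75. Tumor-like WBC numbered 0 of 46 cells, which allows a share of up to 6.52%. All 43 CTC were tumor-like, and 0 of 43 were intermediate, which allows a share of up to 6.98%. Intervals and upper limits cover counting error only, and cells of 1 sample are not independent.

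The 5 samples that held at least 3 cells of each class all have names that begin with C, so the P samples do not enter here. In them, 229 of 237 bins of chromosome 6 were higher in DP cells than in WBC (mean difference 0.32). Lower in DP cells were 197 of 214 bins of chromosome 14 (-0.20), 135 of 154 of chromosome 18 (-0.21) and 247 of 256 of X (-0.67). The mean X level itself was -0.621 ± 0.316 in DP cells and 0.0300 ± 0.0537 in WBC on the log2 scale (SD, n = 5 samples), against -1.14 ± 0.0349 in CTC.

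Growth signalling genes moved one way. Of 11 measured, 6 were higher in DP cells, among them Braf, Met and Akt1, and 5 did not pass. Met rose by 0.40 (SE 0.0613, limma adjusted p = 0.00677), Braf by 0.37 (SE 0.0680, adjusted p = 0.00712) and Akt1, a kinase of survival signalling, by 0.23 (SE 0.0355, adjusted p = 0.00677). Of 10 melanocyte genes, Mitf was higher (0.46, SE 0.0720, adjusted p = 0.00677) and 4 were lower. The lower ones were Dct, the pigment granule protein Pmel, the melanocortin receptor Mc1r and the transporter Slc45a2, with Dct at -0.38 (SE 0.0615, adjusted p = 0.00677) and Slc45a2 at -0.22 (SE 0.0428, adjusted p = 0.00835). Of 15 cell cycle and tumor suppressor genes 6 were lower and 0 higher. They were Cdk4 (-0.26, SE 0.0542, adjusted p = 0.00913), Mdm2 (-0.24, SE 0.0494, adjusted p = 0.00913), Apc (-0.22, SE 0.0459, adjusted p = 0.00957), Arid1a, and Cdkn2a with Cdkn2b, which lie in 1 bin. Adjusted over the list alone, 7 of these 15 were lower and 1 higher, and the counts of the growth signalling and melanocyte lists were the same. The genes given with an adjusted p had the same direction in 5 of 5 samples. When classes of at least 1 cell entered, which added C2N, the bins of Cdk4 and Arid1a no longer passed, and among cells below the median noise those of Mdm2 and Arid1a did not.

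The score of DP cells was 0.574 ± 0.254 in these samples, and its difference from WBC was 0.562 ± 0.264, above 0 in 5 of 5 samples (two-sided exact sign-flip test, p = 0.0625). The tumor-like share averaged 60.4% ± 26.1 in DP cells and 0% in WBC, and the intermediate share 9.41% ± 4.59 and 0% (exact p = 0.0625 each). The X level differed by -0.651 ± 0.306 (exact p = 0.0625) in DP cells and by -1.17 ± 0.0615 (exact p = 0.0625) in CTC. By limma 1708 of 4376 bins passed, 644 higher and 1064 lower. This count fell to 982 without C1L and to 975 without C2R. In lung cells, with 3 samples, the DP minus WBC differences were 0.0864 in score, 8.98% in tumor-like share, 1.33% in intermediate share and -0.0799 in X level. The intermediate share difference was 14.2% in blood cells, 4.09% with limits of 0.35 and 0.65, and 0.369% (SD 9.09, exact p = 0.9375) when bins at the ceiling of the deposited values were included, which gave mean shares of 5.24% in DP cells and 4.87% in WBC. Bin-to-bin noise was 0.169 ± 0.00693 in DP cells, 0.167 ± 0.0132 in CTC and 0.168 ± 0.0142 in WBC, with mean differences from WBC of 0.00129 ± 0.00885 for DP (exact p = 0.8125) and -0.000771 ± 0.0116 for CTC (exact p = 0.875). With a pseudocount of 0.5, both were above WBC in 5 of 5 samples, by 0.0101 and 0.0125 (exact p = 0.0625 each).

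**Figure D2:**
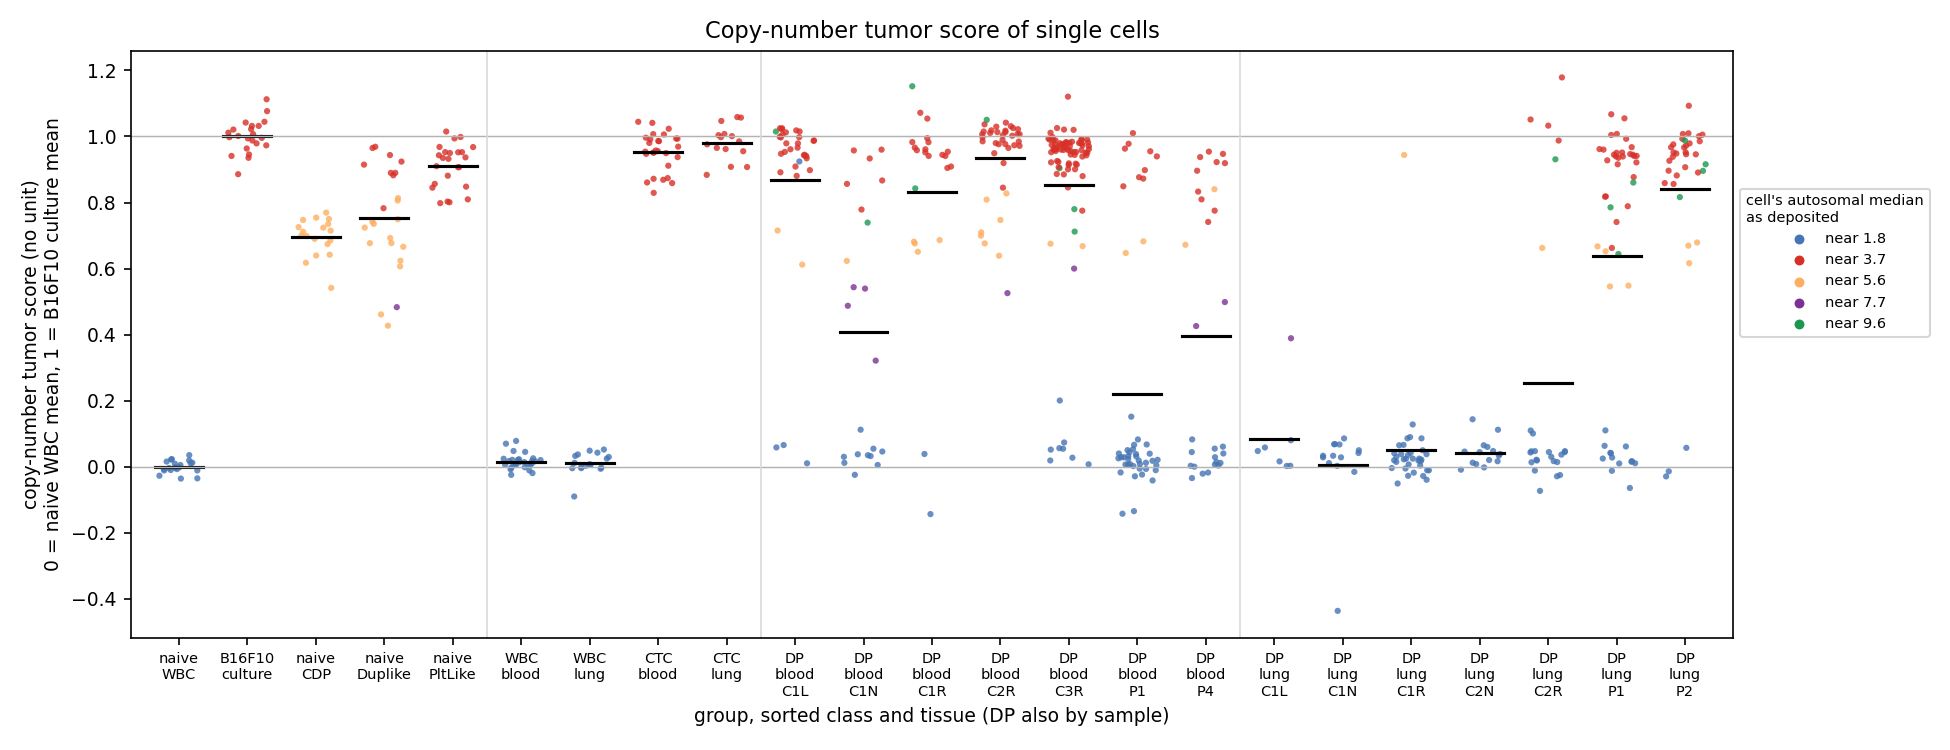
Copy-number tumor score of single cells (vertical axis, no unit; 0 is the naive WBC mean and 1 the culture mean) by class, tissue and, for DP cells, sample (horizontal axis), with 1 point per cell, color for the level near which the deposited autosomal median lies, and bars for group means. CTC lie near 1 and WBC near 0, while DP cells fall into both clusters with 40 of 450 between 0.25 and 0.75.

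CTC were compared with DP cells to ask whether the DP class as a whole differs from sorted tumor cells. The chromosomes that differed between culture and naive WBC also differed between these classes. CTC were higher than DP cells at 171 of 237 bins of chromosome 6 (mean difference 0.24), and lower at 100 of 214 of chromosome 14 (-0.13), 67 of 154 of chromosome 18 (-0.13) and 246 of 256 of X (-0.52). Mitf was higher in CTC (0.34) and Dct and Pmel were lower (-0.23 and -0.16). Of the growth signalling genes 3 of 11 were higher, and adjusted over the list alone 4 were. Of the cell cycle and tumor suppressor genes 3 of 15 were lower. Adjusted over the list alone, the counts of this list and of the melanocyte list were the same.

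The score difference was 0.371 ± 0.243, above 0 in 5 of 5 samples and from 0.122 to 0.643 (two-sided exact sign-flip test, p = 0.0625). By limma 1048 of 4376 bins passed, 414 higher and 634 lower in CTC. This count was not stable when a sample was left out. By limma, 0 bins passed without C1N, C1R or C2R, where the smallest adjusted p was 0.0518, 0.0585 and 0.0603. At an unadjusted p under 0.05 stood 1317, 1202 and 1342 bins. The count was 587 without the sample block and 70 in blood cells. It was 0 (limma, 302 at an unadjusted p under 0.05) when DP cells were restricted to those near 3.7. With that restriction the score difference was -0.0136 ± 0.0401 (exact p = 0.8125). All 43 CTC lay near 3.7, and DP cells had a mean score of 0.955 near 3.7 and 0.0292 near 1.8. The restriction thus kept DP cells that already resembled CTC, so a small difference was largely built in. The score difference was 0.166 in blood cells and 0.816 in lung cells, the latter from 2 samples.

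DP cells of lung and blood were compared because the labels give both tissues. The tumor-like share of blood DP cells was 90.9% in C1L, 91.3% in C1R, 100% in C2R and 45.5% in C1N, and that of lung DP cells of the same samples was at most 24% (6 of 25 cells, in C2R). The blood mean scores were 0.867 (C1L, 33 cells), 0.407 (C1N, 22), 0.831 (C1R, 23) and 0.936 (C2R, 39), and the lung means 0.0854 (7 cells), 0.00492 (14), 0.0514 (34) and 0.254 (25). Sample P1 ran the other way, with 0.221 in blood (46 cells) and 0.638 in lung (47 cells). Of the samples with 1 tissue, C3R blood had 0.852, P4 blood 0.395, C2N lung 0.0427 and P2 lung 0.841. Over the 5 samples with both tissues the score was 0.207 ± 0.259 in lung and 0.652 ± 0.318 in blood, a difference of -0.446 ± 0.506 that was negative in 4 samples and positive in 1 (two-sided exact sign-flip test, p = 0.1875). Without P1 the difference was -0.661 ± 0.179 (exact p = 0.125, the smallest that 4 pairs allow).

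Each cell was assigned to 1 of 5 levels of deposited coverage, whose autosomal medians lay near 1.82, 3.72, 5.64, 7.75 and 9.59. The descriptions do not state a reason for these levels. A DP cell of C1L blood with a median of 2.44 lay between 1.82 and 3.72 and was counted near 1.8. All 67 WBC lay near 1.8 and all 43 CTC near 3.7. DP cells divided into 177 near 1.8 (39.3%), 219 near 3.7 (48.7%), 29 near 5.6 (6.44%), 9 near 7.7 and 16 near 9.6. DP cells near 1.8 had a mean score of 0.0292 and those near 3.7 one of 0.955. Those near 5.6 and 7.7 lay between the controls, at 0.687 ± 0.0827 (SD over cells, in 8 samples) and 0.481 ± 0.0872 (in 5 samples), and their X levels of -0.62 and -0.38 lay between those of CTC and WBC. DP cells near 9.6 had a mean score of 0.877 ± 0.133.

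The bins with the most positive and the most negative difference between culture and naive WBC, a choice made after the profiles were seen, gave almost opposite signals in host and line. The first, a bin of chromosome 14 from 52958219 to 53528636, which holds 54 V segments of the T cell receptor alpha locus Tcra, stood at 0.00649 ± 0.00501 of the autosomal median in 67 WBC and at 0.439 ± 0.0737 in 43 CTC. The other, a bin of X from 87239364 to 87785367, inside Il1rapl1, which encodes a synaptic adhesion protein, stood at 1.02 ± 0.103 in WBC and 0.160 ± 0.0462 in CTC. DP cells near 5.6 had 0.315 at Tcra and 0.609 at Il1rapl1. Both loci lay above their limits, the highest WBC value at Tcra (0.0243) and the highest CTC value at Il1rapl1 (0.254), in 38 of 38 DP cells near 5.6 or 7.7, in 9 of 16 near 9.6, in 51 of 219 near 3.7 (23.3%) and in 20 of 177 near 1.8. They did so in 0 of 43 CTC, 0 of 67 WBC and 0 of 22 culture cells, but the limits were set on the CTC and WBC themselves. Within 8 samples, DP cells near 5.6 or 7.7 differed from DP cells near 3.7 by -0.138 ± 0.0317 at Tcra, by 0.436 ± 0.0306 at Il1rapl1 and by -0.313 ± 0.0550 in score (two-sided exact sign-flip tests, p = 0.00781 each, the smallest p that 8 pairs allow). The levels belong to the same deposited coverage. If they were fitted to each cell's profile, such differences would be built in.

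**Figure D3:**
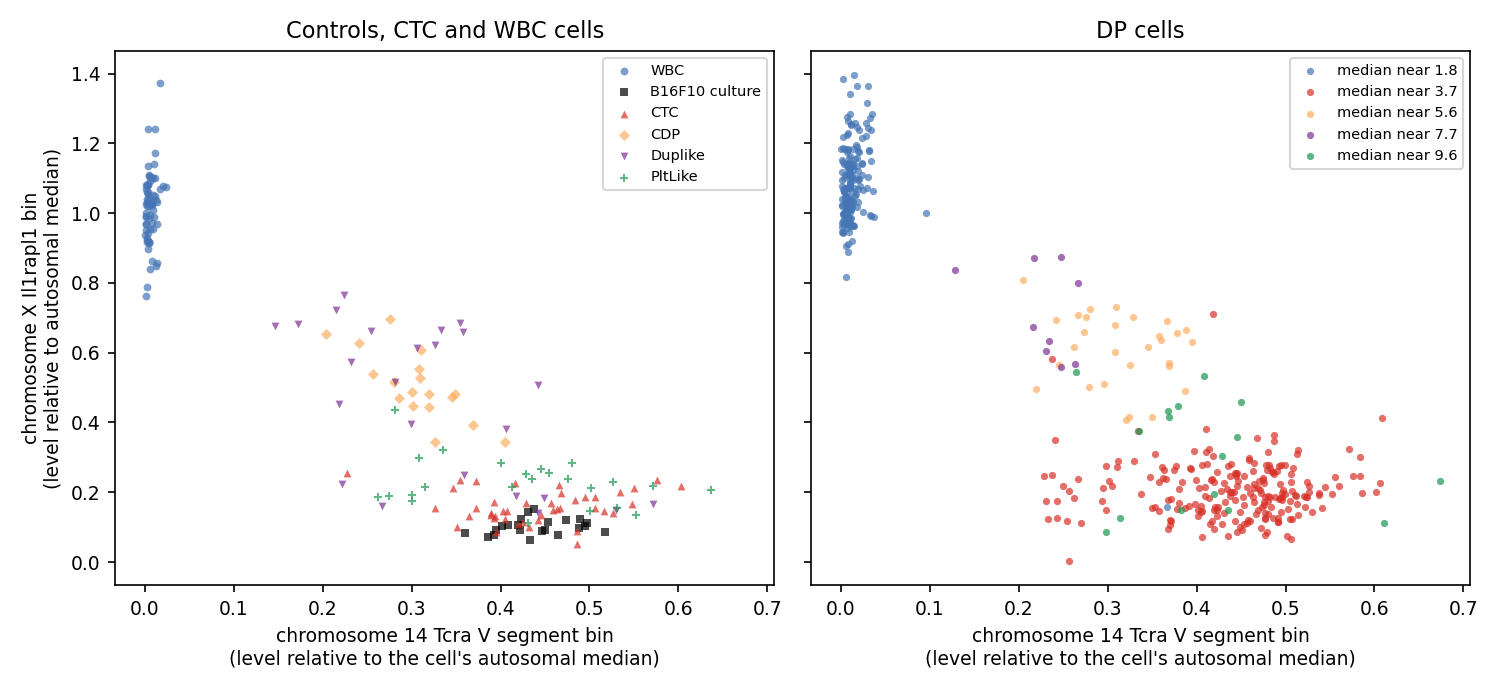
Coverage of the Tcra bin (horizontal axis) against the Il1rapl1 bin (vertical axis), both relative to the autosomal median of the cell and without unit, with 1 point per cell, for the controls, CTC and WBC on the left and for DP cells on the right, colored by the level near which their deposited median lies. WBC stand near 0 at Tcra and near 1 at Il1rapl1, CTC average 0.439 and 0.160, and most DP cells near 5.6 and 7.7 lie between them.

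The CDP, Duplike and PltLike controls were compared with the culture and naive WBC as background for intermediate scores. PltLike cells lay near the culture, while all 18 CDP cells (0.542 to 0.769) and the 15 of 24 Duplike cells near 5.6 or 7.7 (0.427 to 0.813) lay below every culture cell (0.886 or more) and above every naive WBC, although the labels give the treatment of all 3 as naive. PltLike cells had a mean score of 0.911 (SD 0.0660 over 24 cells) and 0 of 24 were intermediate, which allows a share of up to 12.5%. CDP cells had a mean score of 0.696 (SD 0.0568), all 18 lay near 5.6, and 15 of 18 (83.3%, 58.6% to 96.4%) were intermediate. Duplike cells had a mean score of 0.752 (SD 0.158), with 21 of 24 tumor-like and 13 of 24 (54.2%, 32.8% to 74.4%) intermediate. Both loci lay above their limits in 18 of 18 CDP, 16 of 24 Duplike and 6 of 24 PltLike cells. Each of these controls is 1 sample, and no test was made.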

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

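All tests in this part were chosen after the results they bear on were seen.

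DP cells whose deposited coverage lies near 5.6 or above made up 12% of all DP cells (54 of 450, 9.14% to 15.4%), a signal in a per-cell level on which the descriptions are silent and at which 0 of 67 WBC, 0 of 43 CTC and 0 of 22 culture cells stood, but 18 of 18 CDP and 15 of 24 Duplike controls did. Against uneven amplification alone stands the Il1rapl1 bin, which moved toward the host level in 8 of 8 samples, by 0.436 ± 0.0306 relative to DP cells near 3.7. The Tcra bin moved toward the host level by -0.138 ± 0.0317. That shift cannot decide on a tumor clone with fewer changes. The value is relative to the autosomal median, so it would also fall in a clone with more copies elsewhere. Both shifts compare groups set by levels of the same coverage, so they weigh less if the levels were fitted to the profiles. Tumor and host DNA in 1 library is a candidate explanation for the cells near 5.6 or 7.7. It rests on 100% of these 38 cells holding both loci above their limits, although 23.3% of DP cells near 3.7 did too. With parts chosen on the assumption that the levels stand for DNA content, which the descriptions do not state, mixtures of the control profiles at 4 tumor parts to 2 host parts gave a score of 0.678 and an X level of -0.71, next to 0.687 and -0.62 observed near 5.6, and 4 to 4 gave 0.518 and -0.49, next to 0.481 and -0.38 observed near 7.7, but at Il1rapl1 the same mixtures gave 0.399 and 0.547, below the 0.609 and 0.713 observed, and 8 to 2 gave a score of 0.805, below the 0.877 observed near 9.6. No value here separates a single cell with both genomes from a pair of cells sorted into 1 well, or from host DNA carried with a tumor cell, so these stay open.

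The lung minus blood difference in DP score was 0.416 in P1 and between -0.782 and -0.402 in the 4 C samples with both tissues. P1 thus ran opposite to each of these. The difference between C and P was not tested, and P holds 1 sample with both tissues. Noisier cells in P1 are argued against by its 14 lung and 14 blood cells below the median noise, where the difference was 0.413. Exchanged tissue labels in the P samples cannot be told apart from a real difference, because the blood value of P4 (0.395) falls between the highest lung value (0.254) and the lowest blood value (0.407) of the C samples, although the lung value of P2 (0.841) falls within their blood range and outside their lung range. A difference in biology between C and P samples stays open as untested, since the labels do not say what the letters stand for.

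The blood CTC of C1N had a mean X level of -1.05 on the log2 scale, far from the other 4 samples (-1.18 to -1.15). It was the 1 group of 21 tested in which a sample stood apart, and chance gives about 1 in 20.

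The counts of bins past the test were compared with 100 of the 126 ways to divide the class means into groups of 5. For CTC minus WBC only the real division, 1 of 100, gave as many bins (2178, highest other 0), and for DP minus WBC 3 of 100 did (1708, highest other 1793), as did 3 of 100 for CTC minus DP (1048, highest other 1506). Most of these divisions keep pairs together, so they do not settle whether chance can be excluded. The other divisions with any calls, 2 for DP minus WBC and 4 for CTC minus DP, kept the real contrast in the samples whose pair they parted. Among the 16 divisions that part every pair, the highest other count was 0 in each comparison, and 16 are too few for a share under 0.05. The CTC minus DP count also fell to 0 without C1N, C1R or C2R (limma, 1317, 1202 and 1342 bins at an unadjusted p under 0.05).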

How the results depend on the processing

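The alternatives that put back the ceiling bins, took DP cells near 3.7 only, or applied the cell minimum and the tissue to the bin counts, as well as all those for the CDP, Duplike and PltLike scores, were chosen after the results were seen. Over 220 alternatives of the 17 results that answer a comparison, 193 kept direction (or, for counts and untested values, stayed within their limits), 7 passed the threshold where the reported value had not, 12 moved and 8 reversed. Over 204 alternatives of single gene bins 198 were unchanged and 6 lost their call. Unchanged means the same call or, for the untested culture values, a shift smaller than the SD over culture cells. The paired tests of 5 or fewer samples could not pass the threshold under any setting, so only direction was at stake there, and the intermediate share difference fell from 9.41% to 0.369% with the ceiling bins (SD 9.09, 3 of 5 samples above 0, exact p = 0.9375), with 5.24% in DP cells and 4.87% in WBC. Without the sample block the same differences had an exact p of 0.00794, namely the scores of DP minus WBC (0.562), CTC minus WBC (0.933) and CTC minus DP (0.371) and the tumor-like (60.4%) and intermediate (9.41%) shares, because unpaired labels allow more permutations, while the CTC minus DP count was 587. With classes of at least 1 cell, which adds 1 pair and so lowers the smallest p to 0.03125, DP minus WBC was 0.474 in score and -0.548 in X level (exact p = 0.03125 each). The added pair, C2N, sets 15 DP cells of lung (mean score 0.0427) against 2 WBC of blood (0.00742), so its tissues do not match. With DP cells near 3.7 only, the CTC minus DP score was -0.0136 and its count 0, which the choice of CTC-like DP cells largely builds in. The CTC minus DP count was 70 in blood cells. Leaving out 1 sample gave counts from 975 to 1761 for DP minus WBC and from 0 to 1140 for CTC minus DP. The noise differences changed sign. DP minus WBC was -0.000388 with at least 10 cells, -0.00162 with a pseudocount of 0.01, -0.000794 in blood and -0.00198 to 0.00330 leaving out 1 sample, and CTC minus WBC was 0.0125 with a pseudocount of 0.5, which weighs more on the lower level of WBC, and -0.00548 to 0.00197 leaving out 1 sample. The CDP score was 0.587 with X added and 0.832 with the ceiling bins. Runs numbered 7 at a limit of 0.5 and 17 at 20 bins, since both are stricter. Where no reason is given, the cause was not tested. The filter on low bins removed none, leaving out samples without a pair changes nothing, and the alternatives for tumor and host variants were not run. The depth of the cells is unknown, and bins of 538 kb (median) limit what can be seen of shorter changes.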

Other observations

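All tests in this part were chosen after the results they bear on were seen.

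The B16F10 culture was not uniform. Its cells differed most on chromosome 19 (SD 0.243 on the log2 scale over 22 cells) and chromosome 12 (SD 0.206), against 0.0418 and 0.0425 in naive WBC. A combination of chromosome 3 below 0.08, chromosome 12 above 0.15 and chromosome 15 above 0.12, with limits set after seeing the cells, marked 4 of 22 culture cells (18.2%, 5.19% to 40.3%). It marked 5 of 24 Duplike, 2 of 24 PltLike, 1 of 18 CDP and 1 of 43 CTC, but 0 of 219 DP cells near 3.7, which allows a share of up to 1.37%, and 0 of 67 WBC. No test between samples was made, since the culture is 1 sample.

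Some host-like DP cells had a chromosome far from its level in naive WBC. Beyond 0.35 stood 10 of 176 DP cells near 1.8 with a host-like score (5.68%, in 5 of 9 samples). Of these, 7 did so at 1 chromosome. Of 67 WBC 0 did, which allows a share of up to 4.48%. The highest WBC deviation, 0.308, lay just under the limit. DP cells near 1.8 had a higher mean noise (0.179, against 0.168 in WBC of tumor-injected mice), so uneven amplification stays open. The difference was not tested. A single DP cell of C1L blood had an autosomal median of 2.44, between levels, and was counted with those near 1.8. It was tumor-like, with a score of 0.924, an X level of -1.03, 0.367 at Tcra and 0.158 at Il1rapl1.

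The Tcra bin held almost no coverage in WBC and 0.439 of the autosomal median in CTC, so sequence that cannot be aligned is argued against. V(D)J rearrangement in host leukocytes is argued against by the next bin toward the J segments, which stood at 0.724 in WBC. A germline copy difference between the hosts and the line may account for the pattern, since the highest WBC value was 0.0243 over 67 cells, though hosts and line are both given as C57BL/6J background. This is a hypothesis found and tested on the same cells.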
